A study of Rattus norvegicus with 16 samples.

How the data were processed

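RNA-seq libraries of 16 rats, from tissue labelled as central amygdala, were analysed from a table of deposited read counts per gene. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was selected on magnetic beads, and libraries were made with a NEBNext kit. Per the submitters' processing notes, Trimmomatic, STAR, HTSeq and DESeq2 were used with the genome build rn7. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may not be told apart. The deposited counts are whole numbers with no normalization, 1 column per library and 1 row for each of 33294 gene symbols, and the columns were matched to samples by the library names in the labels. No row named anything other than a gene, and 5345 genes had no count in any library.

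Samples were grouped by exposure and sex as the labels give them: 6 fentanyl males, 6 saline males, 2 fentanyl females and 2 saline females. Library numbers in the labels run from 1 to 6 in fentanyl males and 1, 2 and 9 to 12 in saline males, and are 1 and 2 in fentanyl females and 10 and 11 in saline females. Over the 120 pairs of libraries the smallest chi-square per gene was 4.08, so no pair agreed within sampling noise and each library counted as 1 sample. 

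Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups (minimum 0.603 CPM), which left 17856. Library sizes were scaled by TMM factors, and a quasi-likelihood model was fitted with robust estimation (glmQLFit, glmQLFTest). The comparison over both sexes had sex as a term, and that of the sexes had exposure as a term. The comparisons in males, in females and of the difference between them were contrasts of a fit of the 4 groups, so the female groups of 2 shared the spread of the males. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. Log2 fold changes are given with standard errors, computed as the fold change divided by the square root of its F statistic. CPM are read counts scaled to a common library size with TMM factors.

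Before the data were examined, 38 gene lists of pathways, receptors, cell types and neighbouring brain regions were fixed, with 1015 entries, of which 18 were matched by an older symbol and 16 were not found. The Y-linked list had too few tested members for a set test (fewer than 5), which left 37. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The genes named were fixed by rule. For both sexes and for males these were genes past the threshold with a mean of at least 1 CPM, up to 12 per direction. For females and for the difference between the sexes they were up to 6 per direction past the threshold, or the 3 with the smallest p, and for the sexes 6 per direction. In each list they were up to 4 members past either adjustment or the one with the smallest p, and all members of the opioid list were named. Some members that the rule would name are not reported. Provisional symbols were named only where a count of 5 or fewer was listed, or after their values were seen. Gene names and the order of genes came from a RefSeq gene table of assembly GRCr8, a newer build than the one used for counting, and no coordinates were taken from it.

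Principal components and list means were computed on log2 CPM with a prior count of 2. List means were compared by exact permutation of 8 against 8 (12870 splits, smallest p 1.554e-04, two-sided), and correlations across libraries by 100000 permutations. The steps were tested on simulated counts with 200 changed genes, drawn from genes with a mean of at least 1 CPM. Counts of each gene were drawn independently, with no shared structure of the libraries such as tissue make-up or litter. The shares found do not cover changed genes under 1 CPM or data with such structure. Over both sexes 53.7% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 8 false calls among 170 over 17670 genes. In males the shares were 46.3%, 82.1% and 98.5%.

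Alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, no sex term, surrogate variables (sva 3.50.0), the replicate number as a block, 1 sex alone, library-number subsets of the saline males, and each library left out in turn. Others were added after seeing the data: striatal and myelin list means as covariates, and sets of libraries left out together. Raw reads were not used here.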

Results

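Poly(A) RNA from tissue of adult rats that the labels give as the central amygdala was sequenced after exposure to fentanyl, a synthetic opioid, or to saline around birth. The central amygdala is a GABAergic output nucleus of the amygdala. Tissue was taken in adulthood, 1 day after the last of a series of sessions whose abbreviation the labels do not spell out. There were 16 libraries in 4 groups: 6 fentanyl males, 6 saline males, 2 fentanyl females and 2 saline females. The labels call them offspring of the 2 exposures. They do not say which animals were littermates, so the p-values below measure the spread between these animals and do not allow for shared litters. Total counts per library ranged from 12879701 to 22426428. Both ends lie in male groups: the lowest was fentanyl male replicate 5 and the highest saline male replicate 3. Mitochondrially encoded genes took 8.44% to 17.7% of the counts, and the highest share was that of fentanyl male replicate 2. Of 33294 genes in the table, 17856 were tested.

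The comparison of 8 fentanyl with 8 saline offspring asks which transcripts differed in adult offspring by perinatal exposure, after the sessions that all of them had. With sex as a term, 9 genes were higher and 5 were lower after fentanyl. Spag6l, a component of the central apparatus of motile cilia, showed the largest difference among the named genes above 1 CPM. Its mean was 24.7 CPM in the fentanyl group (range 13.9 to 45.5, n = 8) and 1.79 ± 0.973 CPM in the saline group (SD, n = 8), a log2 fold change of 3.75 ± 0.33 (SE; adjusted p = 5.825e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Efcab1, a calcium-binding protein of ciliary dynein arms, was higher by 1.75 ± 0.22 on the log2 scale. Ift140, a subunit of the intraflagellar transport complex that builds cilia, rose from 53.4 ± 1.75 to 76.3 ± 9.20 CPM, a log2 fold change of 0.51 ± 0.07. Every fentanyl library lay above every saline library for these 3 genes.

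The other higher genes were Ltbp2, a latent TGF-beta binding protein of the extracellular matrix (log2 fold change 1.40 ± 0.20, adjusted p = 0.00622), Magix, a PDZ-domain protein (1.66 ± 0.28, adjusted p = 0.0238), and Calr3, a calreticulin family chaperone (0.86 ± 0.11, adjusted p = 0.00188). Rgs22, a regulator of G protein signalling, was lower by a log2 fold change of -2.21 ± 0.39, at 0.489 ± 0.155 CPM against 2.28 ± 1.81 CPM. Set (-1.38 ± 0.23) and Lonrf3, a protein with LON and RING finger domains (-0.46 ± 0.08), were lower as well. The remaining calls were 5 genes with provisional symbols. LOC100912028 (log2 fold change 3.61 ± 0.43) and LOC120095234 (2.79 ± 0.40) were higher after fentanyl, and LOC310926 (-2.29 ± 0.34) was lower. LOC120098153, at 0.409 ± 0.209 CPM against 0.0222 ± 0.0307 CPM, was higher and LOC120095044, at 0.0961 ± 0.125 CPM against 0.840 ± 0.226 CPM, was lower, both near the lower end of what the depth can count. Set is counted at a low level here and has many pseudogene copies, and Spag6l lies next to LOC100912028 in the gene order, and whether reads were shared or lost between near-identical copies was not tested, so their values are uncertain.

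**Figure D1:**
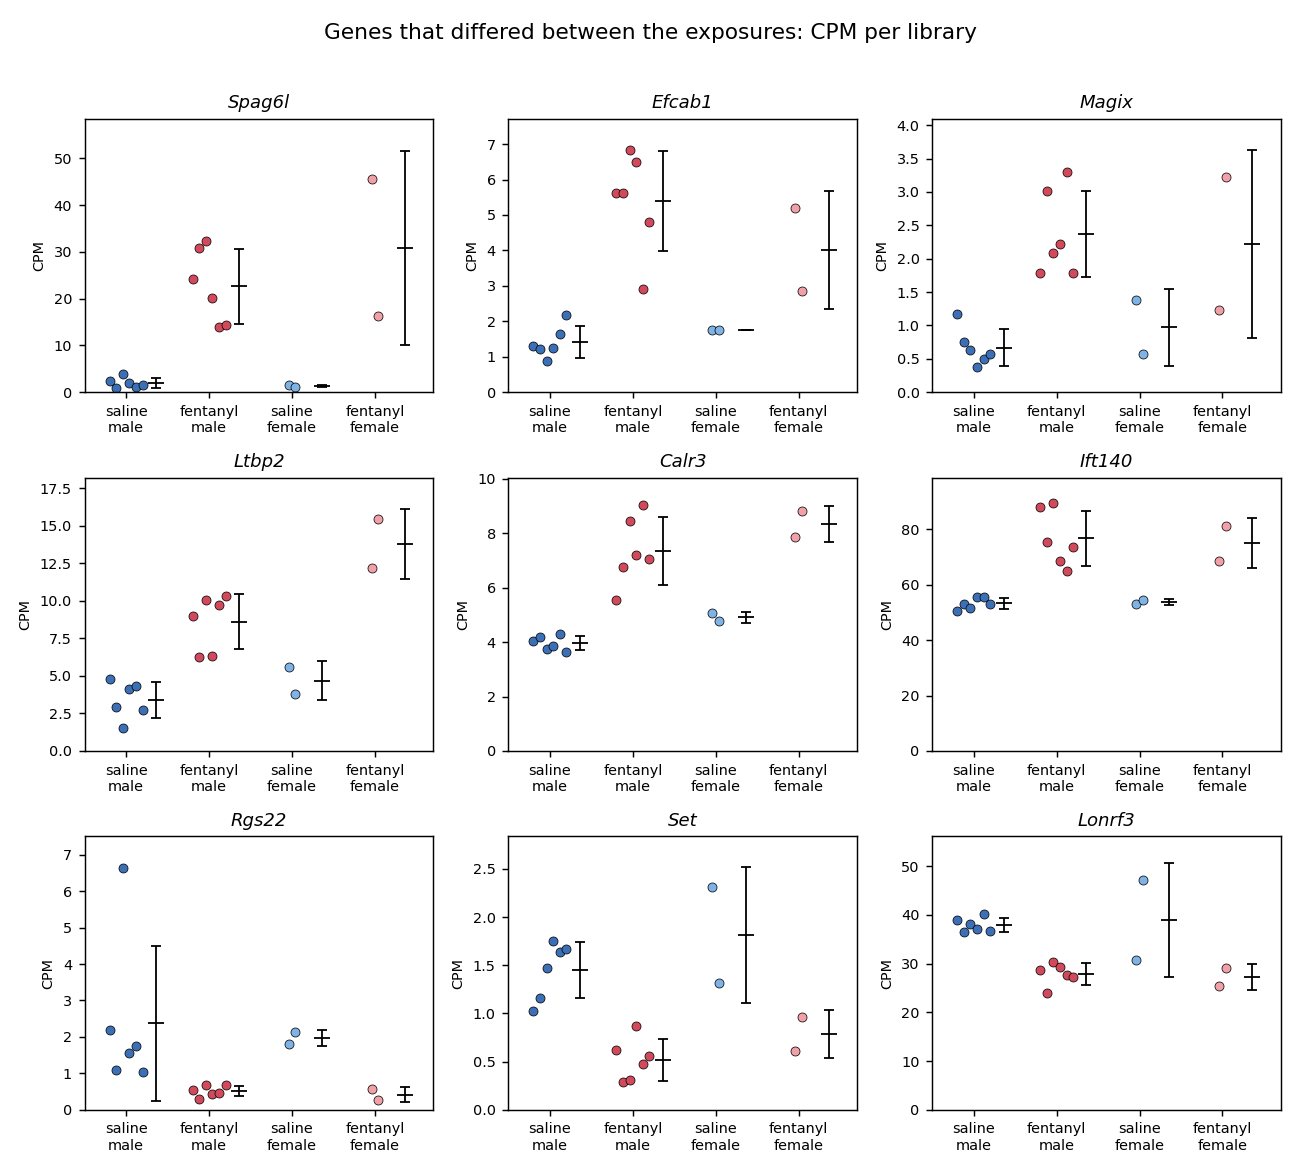
CPM per library (vertical axis, linear, from 0) of the 9 genes with a standard symbol that differed between the exposures, by group. Each dot is 1 library and the bars give the mean ± SD of the group (n = 6 per male group, n = 2 per female group). For Spag6l the fentanyl libraries lie between 13.9 and 45.5 CPM and the saline libraries between 0.811 and 3.90 CPM.

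Of the 14 genes, 11 had no overlap between the 8 fentanyl and the 8 saline libraries. Over all genes tested, 18 had none, against 2.77 expected when a random split of 8 against 8 leaves no overlap in 0.0155% of splits. At an unadjusted p under 0.05 there were 1298 genes, against 893 expected by chance. The number of calls depended on the tool and on which saline libraries were used: DESeq2 called 53 genes higher and 34 lower, limma voom with sample quality weights 663 and 343, and a fit with 3 surrogate variables 54 and 29. Without the saline males with library numbers 1 and 2, a setting chosen after seeing the data, 752 genes were higher and 474 lower, and all 14 genes were among the calls of each of these 4 settings. Each of the 4 called more genes than the main fit, so this is a weak check. Leaving out 1 library at a time gave 8 to 21 higher and 1 to 8 lower genes, with 21 and 8 without saline male replicate 2 and 1 lower gene without fentanyl male replicate 6 or fentanyl female replicate 1. With the striatal and myelin list means as covariates, also chosen after seeing the data, 8 genes were higher and 3 lower, of which 6 and 1 were among the 14, and Ltbp2, Magix, Rgs22, Set, Lonrf3, LOC120098153 and LOC120095044 no longer passed. Rgs22, Lonrf3, Set, Magix and LOC120095044 each fell short of the threshold without some single libraries and kept their direction.

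Among gene lists fixed before the data were examined, 4 of 37 were higher and 4 lower after fentanyl over both sexes by camera with a preset correlation. Random splits of the libraries within sex called as many lists or more in 85 of 100 splits, the real one included. With 1 library left out, 3 lists (without saline female replicate 2) to 20 lists (without fentanyl male replicate 2) were called. Markers of striatal medium spiny neurons had a median log2 fold change of 0.46, and 21 of 21 members had a fold change above 0 (adjusted p = 2.446e-13, but adjusted p = 0.993 with an estimated correlation). Over all genes no member passed, and adjusted over the list alone 1 did. Central amygdala neuron markers, which share 6 genes with the striatal list, had a median of 0.13, with no member past the test over all genes and 1 adjusted over the list alone. Potassium channels (median 0.04) and calcium and sodium channels (median 0.13) were higher with no member past either adjustment. Their members with the smallest p were Kcnk2, a two-pore potassium channel (0.76 ± 0.23, adjusted p = 0.415), and Cacnb3, a calcium channel beta subunit (0.53 ± 0.16, adjusted p = 0.399). These 3 calls were lost with an estimated correlation as well (adjusted p = 0.993 with an estimated correlation for each). Leaving out 1 library moved these medians. The striatal median was 0.70 and that of calcium and sodium channels 0.19 without saline male replicate 2. The potassium channel median lay between 0.03 without fentanyl male replicate 5 and 0.16 without fentanyl male replicate 2 or saline male replicate 3. Without fentanyl female replicate 2 the median of the central amygdala list was -0.01 and its call was lost (adjusted p = 0.0833), and without saline male replicate 3 its median was 0.25.

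The lower lists were extracellular matrix and perineuronal net genes (median log2 fold change -0.20, 22 of 25 members below 0), microglia and macrophage markers (-0.17, 19 of 22), astrocyte markers (-0.15, 18 of 20) and cholesterol biosynthesis genes (-0.08, 18 of 22). Each had an adjusted p = 0.993 with an estimated correlation. F3, tissue factor, which astrocytes express, was the astrocyte member past the test adjusted over the list alone (-0.48 ± 0.11; adjusted over the list alone, adjusted p = 0.0105). In the others the smallest p belonged to Has1, a hyaluronan synthase (-0.62 ± 0.21, adjusted p = 0.493), P2ry12, a microglial purinergic receptor (-0.47 ± 0.19, adjusted p = 0.633), and Mvk, mevalonate kinase (-0.45 ± 0.13, adjusted p = 0.399), none of which passed. Myelin markers had 26 of 27 members below 0 and a median of -0.18 without being called (adjusted p = 0.214). Without saline female replicate 2 the medians of the microglial and astrocyte lists were -0.10 and -0.09, and without saline male replicate 6 that of the cholesterol list was -0.05, each no longer called (adjusted p = 0.0545, 0.134 and 0.182). With the striatal and myelin list means as covariates, chosen after seeing the data, none of the 4 lower lists was called. No list was called by fry either (smallest adjusted p = 0.672).

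In the lists that were not called, medians ran from -0.30 for diencephalic and pallidal markers to 0.08 for glutamate receptor subunits. No member of them passed over all genes. Adjusted over the list alone, 1 member passed in each of 4 of these lists. Rgs4, a brake on Gi-coupled receptor signalling in the list of opioid receptor signalling partners, was higher by 0.65 ± 0.14 on the log2 scale (160 CPM in saline and 254 CPM in fentanyl; adjusted over the list alone, adjusted p = 0.00811). Lamp5, an interneuron marker in the GABA list, had a log2 fold change of 0.75 ± 0.15 (adjusted over the list alone, adjusted p = 0.00333), Mef2c, an activity-regulated transcription factor, 0.48 ± 0.13 (adjusted p = 0.0314), and RT1-A2, a class I histocompatibility gene, 0.89 ± 0.21 (adjusted p = 0.0180). Over all genes, their adjusted p-values by edgeR's quasi-likelihood test lay between 0.119 for Lamp5 and 0.334 for Mef2c. The immediate early genes (median -0.03), glucocorticoid-responsive genes (-0.19), clock genes (0.06), corticotropin-releasing factor and stress peptides (-0.08), cytokines (-0.04), ribosomal proteins (-0.01) and chromatin regulators (-0.02) had no member past either adjustment. For some lists that were not called, such as the immediate early genes and the cortical and basolateral glutamatergic markers, the median and the direction of the test differed in sign.

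**Figure D2:**
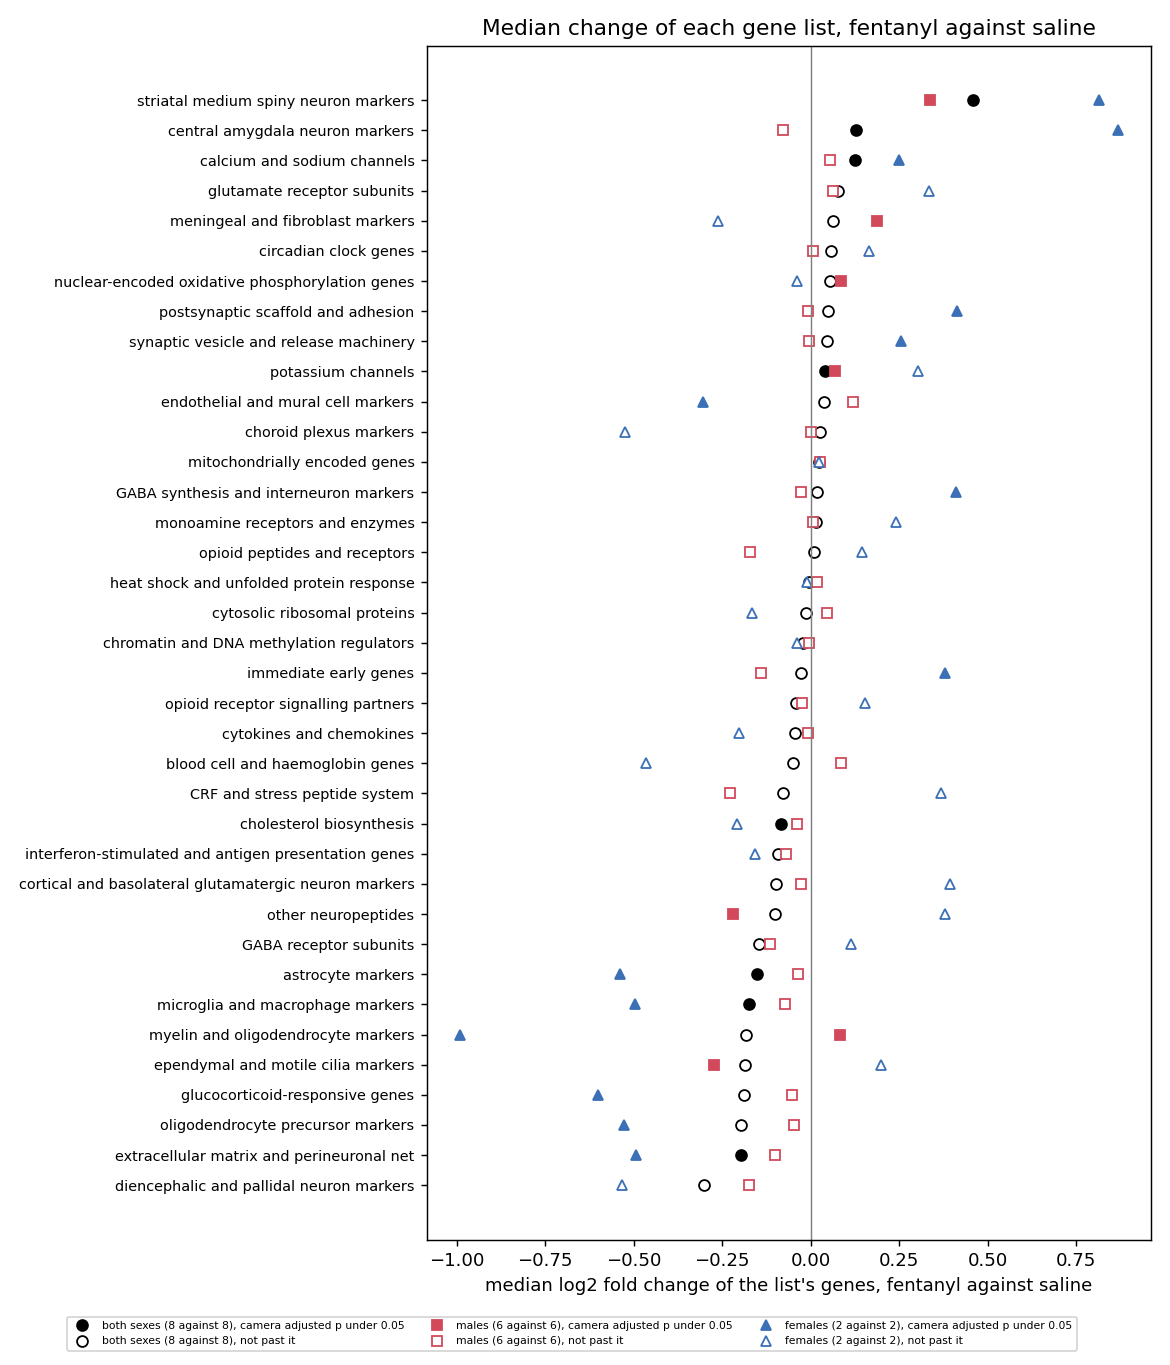
Median log2 fold change, fentanyl against saline (horizontal axis), of the 37 gene lists tested as sets, over both sexes (circles, 8 against 8 libraries), in males (squares, 6 against 6) and in females (triangles, 2 against 2). Filled symbols passed adjusted p under 0.05 by camera with a preset correlation, and none did with an estimated correlation. The striatal list lies at 0.46, 0.34 and 0.81.

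The 8 opioid peptide and receptor genes were detected and tested, and none differed between the exposures over all genes or adjusted over the list alone. Penk, the enkephalin precursor, was the most abundant at 1158 ± 787 CPM in saline and 1477 ± 657 CPM in fentanyl (SD, n = 8 each; log2 fold change 0.32 ± 0.36). Pdyn, the dynorphin precursor, had 257 ± 138 and 275 ± 84.9 CPM. The kappa receptor gene Oprk1 had 19.6 ± 8.67 and 18.5 ± 5.04 CPM, the nociceptin receptor gene Oprl1 18.0 ± 7.82 and 15.5 ± 7.01 CPM, and the mu receptor gene Oprm1 2.44 ± 1.70 and 1.76 ± 1.16 CPM, in saline and fentanyl. Oprd1, the delta receptor gene, had the smallest p of the list (log2 fold change 0.45 ± 0.22, adjusted p = 0.708). Pnoc (-0.28 ± 0.49) and Pomc (0.11 ± 0.25) were low, at 3.15 and 0.967 CPM on average.

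In males alone, 6 against 6, 7 genes were higher and none was lower after fentanyl by edgeR's quasi-likelihood test, with 738 genes at an unadjusted p under 0.05 against 893 expected by chance. Spag6l had 22.6 ± 7.94 CPM in fentanyl males and 1.93 ± 1.11 CPM in saline males (SD, n = 6 each), a log2 fold change of 3.52 ± 0.37. Efcab1 (1.93 ± 0.25), Calr3 (0.89 ± 0.12) and Ift140 (0.53 ± 0.09) were higher too, together with LOC120095234 (3.74 ± 0.25), LOC100912028 (3.40 ± 0.50) and LOC120098153. DESeq2 called 28 genes higher and 14 lower, and limma voom with quality weights 50 and 34, with 6 of the 7 genes among them. Without saline male replicate 4, 4 genes were higher. Without saline male replicate 5, 2 genes were lower. The count changed with the saline libraries used: 57 higher and 14 lower genes without library numbers 1 and 2, and 582 and 373 without numbers 9 to 12, with all 7 genes among the calls in each case. A fit chosen after seeing the data compared fentanyl males with each of the 2 saline number sets. Of the genes called against both sets, 8 had the same direction, the 7 genes and LOC310926, and 9 had opposite directions.

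Of the lists, 5 were higher and 2 lower in males by camera with a preset correlation, and 98 of 100 splits of the males, the real one included, called as many or more. Those that were higher were striatal markers (median log2 fold change 0.34, but -0.48 without saline males 9 to 12), meningeal and fibroblast markers (0.19), nuclear-encoded oxidative phosphorylation genes (0.08), myelin markers (0.08) and potassium channels (0.07). The lower ones were ependymal and motile cilia markers (-0.27) and neuropeptides other than the opioids and stress peptides (-0.22). None was called with an estimated correlation: the ependymal list had adjusted p = 0.499 with an estimated correlation and the other 6 adjusted p = 0.988 with an estimated correlation. Adjusted over the list alone, Dcn, decorin (0.75 ± 0.16), and Col3a1, a fibrillar collagen (0.59 ± 0.18), were higher and Bmp6 (-0.54 ± 0.15) was lower in the fibroblast list. Outside the called lists, Lamp5 (0.69 ± 0.18) in the GABA list and Abcg2, a transporter of brain endothelium (0.91 ± 0.23), in the endothelial list passed when adjusted over the list alone. By library number, the mean log2 CPM of meningeal markers was 2.22 ± 0.18 in fentanyl males (SD, n = 6), 1.72 ± 0.02 in saline males 1 and 2 (n = 2) and 2.13 ± 0.17 in saline males 9 to 12 (n = 4), and that of myelin markers was 7.86, 6.73 and 8.04, above the first of these and below the second. The ependymal markers had 1.28, 1.25 and 1.40 in saline male replicates 1 to 3, against 0.92 to 0.95 in replicates 4 to 6 and 0.71 to 0.94 in fentanyl males. In the ependymal list the smallest p was that of Rsph4a, a radial spoke protein of cilia (-1.46 ± 0.54, adjusted over the list alone, adjusted p = 0.189), and in the neuropeptide list that of Cartpt (-2.37 ± 0.72, adjusted p = 0.108). Neither passed.

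In females, 2 against 2 with the spread shared with the males, no gene passed by edgeR's quasi-likelihood test, with 2555 genes at an unadjusted p under 0.05, 20 calls by DESeq2 and 0 by limma voom. Spag6l had the smallest p, at 30.9 ± 20.8 CPM in fentanyl and 1.38 ± 0.261 CPM in saline females (SD, n = 2 each; log2 fold change 4.48 ± 0.68, adjusted p = 0.120). Next were Fbln2, an extracellular matrix fibulin (-0.90 ± 0.19), and A2m, alpha-2-macroglobulin (-1.62 ± 0.34), each with an adjusted p of 0.333. All of these were among the DESeq2 calls, with an adjusted p of 8.663e-09 for Spag6l, 0.0182 for Fbln2 and 0.0111 for A2m. On simulated data this comparison found 1.49% of genes changed 1.5-fold, 37.3% of those changed 2-fold and 78.8% of those changed 4-fold. A fit of the 4 female libraries alone called 65 genes, and without saline male replicate 5, 5 genes were called. The library numbers were 1 and 2 in fentanyl females and 10 and 11 in saline females, so exposure cannot be told apart here from a difference between number sets such as that among saline males.

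By camera with a preset correlation 7 lists were higher and 7 lower in females. Those that were higher were central amygdala markers (median log2 fold change 0.87), striatal markers (0.81), postsynaptic scaffold genes (0.41), GABA and interneuron markers (0.41), immediate early genes (0.38), release machinery (0.25) and calcium and sodium channels (0.25). The lower ones were myelin markers (-0.99, 27 of 27 members below 0), glucocorticoid-responsive genes (-0.60), astrocyte markers (-0.54), oligodendrocyte precursor markers (-0.53), microglia markers (-0.50), extracellular matrix genes (-0.49) and endothelial markers (-0.30). All 14 had an adjusted p = 0.683 with an estimated correlation. Adjusted over the list alone, Mylk (-0.94 ± 0.25) and Notch3 (-0.81 ± 0.22), both of mural cells, Vcan (adjusted p = 0.0496) and Timp1 (-1.12 ± 0.33) of the matrix list, and Dnah5 (-1.34 ± 0.39) and Foxj1 (-0.80 ± 0.25) of the ependymal list passed, the last 2 in a list that was not called and whose median was 0.20. Mean log2 CPM of the myelin list was 7.67 and 6.58 in the 2 fentanyl females and 8.21 and 8.26 in the 2 saline females.

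No gene passed the test of the difference of the fentanyl effect between the sexes by edgeR's quasi-likelihood test, with 1470 genes at an unadjusted p under 0.05, 4 calls by DESeq2 and 0 by limma voom. Among genes with a standard symbol the smallest p belonged to Spata1, a spermatogenesis-associated gene (log2 difference -1.56 ± 0.36), RT1-N2, a class Ib histocompatibility gene, and Wee2, an oocyte kinase (-3.14 ± 0.73), each with an adjusted p of 0.570. RT1-N2 had no count in either saline female and 0.0544 CPM in saline male replicate 5, against 2.68 to 6.04 CPM in the other libraries. LOC120095234, the gene with the smallest p of this comparison (adjusted p = 0.0729), had 3.41 ± 0.918 CPM in saline females and 0.407 ± 0.102 CPM in saline males, and 5.68 ± 0.232 and 5.48 ± 1.78 CPM in fentanyl females and males. Without a sex term its difference between the exposures did not pass (2.27, adjusted p = 0.131).

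Across the 17856 genes, the log2 fold changes of males and of females, which share no library, correlated with Pearson's r = 0.177 and Spearman's rho = 0.153. Genes are not independent replicates, and 45 of 100 regroupings of the labels within sex gave an r as large, so the agreement did not exceed chance. For the 10515 genes with a mean of at least 10 CPM, r was 0.166, and 70 of 100 regroupings reached it.

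The comparison of 12 males with 4 females served as a check of the sex labels. Eif2s3y, Ddx3, Uty and Kdm5d were the male-higher genes with a standard symbol among 7. Eif2s3y, a translation factor subunit encoded on the Y chromosome, had 54.3 ± 3.09 CPM in saline males and 0.0628 ± 0.0888 CPM in saline females (adjusted p = 2.107e-14). Of the 3 female-higher genes, Eif2s3, its X-linked counterpart, had 144 ± 12.3 CPM in saline females and 82.6 ± 7.79 CPM in saline males (log2 male minus female -0.70 ± 0.07, adjusted p = 7.637e-05). No library went against its label in these genes.

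The make-up of the libraries was described by principal components and by marker lists. The first component (28.7% of the variance) followed the microglial list, and neither it (two-sided exact permutation p = 0.307) nor the second (19.2%, p = 0.271) differed between the exposures. The fourth component (6.32%) separated all 8 fentanyl from all 8 saline libraries (n = 8 each; two-sided exact permutation p = 1.554e-04, the smallest the design allows, adjusted p = 6.216e-04 over 4 components). Of 15 composition lists none differed after adjustment. Striatal markers had a mean log2 CPM of 7.94 ± 0.34 in fentanyl and 7.38 ± 0.64 in saline (two-sided exact permutation p = 0.0480, adjusted p = 0.604). Next came the ependymal markers, with 0.92 ± 0.13 and 1.07 ± 0.20 (exact permutation p = 0.0805).

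Across the 16 libraries, the striatal list fell as glial lists rose. With the microglial list Pearson's r was -0.814 (permutation p = 1.600e-04) and Spearman's rho -0.750 (p = 0.00126), with the astrocyte list -0.708 (p = 0.00234) and -0.785 (p = 6.000e-04), and with the myelin list -0.586 (p = 0.0168) and -0.671 (p = 0.00573). After Benjamini-Hochberg adjustment over the 3 relations, the p-values of r were 4.800e-04, 0.00351 and 0.0168. Leaving out the 2 libraries farthest from the striatal median gave r of -0.837, -0.837 and -0.796. Within the fentanyl libraries r was -0.760, -0.844 and -0.789, and within the saline libraries -0.810, -0.633 and -0.588 (n = 8 each).

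The saline males differed in striatal markers by library number. These markers had a mean log2 CPM of 8.22 ± 0.29 in numbers 1 and 2 (SD, n = 2) and 6.89 ± 0.37 in numbers 9 to 12 (SD, n = 4), with the fentanyl males at 7.80 ± 0.22 (SD, n = 6). Myelin markers had 6.73 ± 0.22, 8.04 ± 0.60 and 7.86 ± 0.25, but did not follow the numbers throughout: saline male replicate 3, number 9, had 7.19, nearer to 6.58 and 6.88 in numbers 1 and 2 than to 8.06, 8.40 and 8.50 in numbers 10 to 12. In males the median log2 fold change of the striatal list was 0.34 with all saline males, 0.84 without numbers 1 and 2, and -0.48 without numbers 9 to 12, so its direction turned with the saline libraries used.

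**Figure D3:**
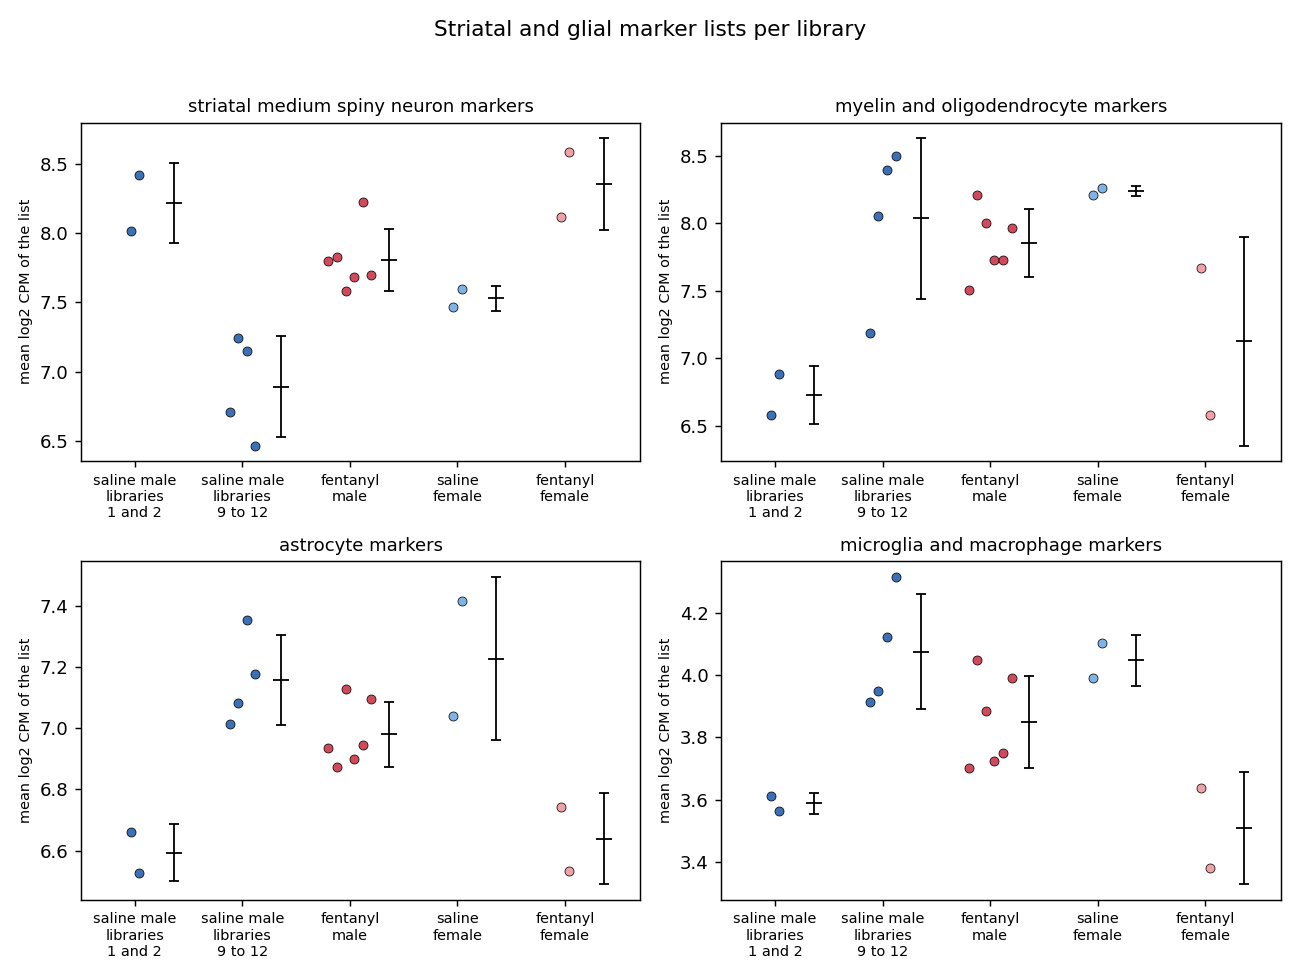
Mean log2 CPM (vertical axis, not starting at 0) of 4 marker lists per library, with the saline males split by library number. Each dot is 1 library and the bars give the mean ± SD. In the striatal panel saline males 1 and 2 have a mean of 8.22, saline males 9 to 12 of 6.89 and fentanyl males of 7.80.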

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

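The tests on ependymal cells, on library numbers and on striatal tissue were chosen after the results were seen. The others were set out before their own outcomes were known, though they address patterns already seen in the results.

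Among 86 tests of the male groups for a library far from the other 5, 10 stood out, against 4.30 expected by chance at 1 in 20. Fentanyl male replicate 2 had 17.7% mitochondrial counts against 8.90% to 10.1% in the other 5 (gap over range 0.860) and a mean log2 CPM of mitochondrial genes of 13.1 against at most 12.2 (0.844). It lay apart on the second component (0.719), was high for endothelial and mural markers (4.30 against at most 3.69; 0.638) and low for cortical and basolateral glutamatergic markers (3.11 against at least 3.47; 0.639). Saline male replicate 3 was high for the same cortical list (4.82 against at most 3.61; 0.692), for Rgs22 (6.63 against at most 2.20 CPM; 0.792), for LOC100912028 (1.59 against at most 0.755 CPM; 0.643) and for Pnoc (10.4 against at most 4.43 CPM; 0.636). Pnoc was also high in fentanyl male replicate 1 (the others were at most 2.44 CPM; 0.886).

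The effect of fentanyl differed between the sexes for 18 lists by camera with a preset correlation on the interaction, and for none with an estimated correlation (smallest adjusted p = 0.619 with an estimated correlation). The median log2 difference, female minus male, was -1.11 for myelin, -0.52 for astrocyte, -0.38 for microglia, -0.42 for endothelial, -0.51 for meningeal, -0.50 for oligodendrocyte precursor, -0.49 for extracellular matrix and -0.50 for glucocorticoid-responsive genes. It was 0.42 for postsynaptic scaffold, 0.73 for central amygdala, 0.30 for release machinery, 0.44 for immediate early, 0.56 for other neuropeptide, 0.33 for calcium and sodium channel, 0.31 for GABA and interneuron, 0.51 for striatal, 0.19 for opioid signalling partner and 0.36 for stress peptide genes. Each female group held 2 libraries, with library numbers 10 and 11 in saline females, whereas saline males had 1, 2 and 9 to 12. The saline females had a mean log2 CPM of striatal markers of 7.47 and 7.59 and of myelin markers of 8.21 and 8.26, so a difference between the sexes cannot be told apart from one between the number sets.

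The 14 genes that differed between the exposures over both sexes form the pattern a reader might follow first, since 11 of them had no overlap between the groups. A chance split of exchangeable libraries can be set aside, since 1 of 100 splits of the libraries, the real one, gave as many genes and the highest other gave 2. The splits do not allow for litters or library numbers. Ependymal cells with motile cilia would raise the whole cilia list with Spag6l and Efcab1, but its upper quartile of log2 fold change was 0.0476 and its largest member stood at 0.20, which argues against them. Inherited variants that differ between the litters of the 2 exposures remain open. The uncalled genes within 10 places of the called ones had a mean absolute z at percentile 97.4 of 10000 random sets of places. The same value stood at percentile 95.5 among random sets of 10 places, the number left when called genes within 50 places count once. The observed value was not recomputed over those 10 places. Inherited variants may account for part of these differences. An effect of perinatal fentanyl itself stays open and cannot be separated from litter without knowing the litters. Most saline libraries had numbers 9 to 12, which no fentanyl library had, so number set is a further limit. In males, 8 of the 14 genes were called in the same direction against saline numbers 1 and 2 and against 9 to 12. Among all genes called against both sets, 9 had opposite directions. Ltbp2, Magix, Rgs22, Set, Lonrf3 and LOC120095044 were not called against both, so number set stays open for them.

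The striatal list was higher and the astrocyte and microglial lists lower after fentanyl over both sexes, but in males the myelin list was higher (median 0.08) and the astrocyte (-0.04) and microglial (-0.07) lists were not called, whereas in the 2 against 2 females all 3 were lower, and with an estimated correlation none of these calls held (adjusted p = 0.993 with an estimated correlation over both sexes, 0.988 in males and 0.683 in females). Chance cannot be excluded for the number of list calls, which random splits mostly reached or passed. At least 8 lists over both sexes were called in 85 of 100 splits, with a median of 13 and a highest of 28 in the others. In males at least 7 were called in 98 of 100, with a median of 16 and a highest of 29 in the others. A difference between the saline male libraries numbered 1 and 2 and those numbered 9 to 12 could give this pattern, since without numbers 9 to 12 the striatal median in males was -0.475, and between these 2 sets 1477 genes were higher and 1724 lower. The share of striatal against glia-rich tissue in the punch cannot be told apart from an effect of exposure: with a glial covariate 86.4% of the striatal median was kept, but leaving out 1 library moved this from 74.6% to 115%. An effect of fentanyl on these cells was not separable from either.

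Striatal markers stood far above central amygdala markers, with a median of 221 CPM for the 15 striatal genes absent from the amygdala list against 16.3 CPM for the 18 amygdala genes absent from the striatal list. Of the striatal genes absent from the amygdala list, Rgs9 stood at 450 ± 211 and Adora2a at 282 ± 130 CPM. Ppp1r1b, which is on both lists, stood at 1464 ± 597 CPM. Of the amygdala markers absent from the striatal list, Prkcd stood at 16.8 ± 5.60 and Sst at 101 ± 46.2 CPM (SD, n = 16). If the share of striatal tissue in place of amygdala varied between punches, the 2 sets of markers may be expected to move apart across libraries. Their correlation was 0.306 within fentanyl and -0.0700 within saline libraries (n = 8 each). A share alike in all punches would leave no such relation, so this test cannot tell whether the punches held striatal tissue. By mean CPM, Rgs9 and Adora2a stood at percentiles 98.8 and 97.2 of the tested genes, against 50.4 for Prkcd, 30.5 for Crh and 87.6 for Sst. These levels leave striatal tissue in the punches possible, but no reference tissue was compared. A biological explanation was not tested.

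The 7 genes called in males had 2 of 100 splits as large, the real one included, so few random splits of the males gave as many. These splits treat the males as exchangeable and do not allow for litters or for the number sets of the saline males. The highest other split called 1215 genes and the next 2. That split parts the males by their order on the first component, with 1 side at -2.97 or above and the other at -4.92 or below, which points to a structure of the samples. For the comparison of the sexes, 1 of 100 splits gave 10 genes, and the highest other gave 2.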

How the results depend on the processing

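All 14 genes called over both sexes kept their direction under each alternative run in which they were tested, and all stayed called with DESeq2, limma voom, surrogate variables and without saline males 1 and 2. Each of these 4 settings called more genes than the main fit, so keeping the 14 is a weak check. Without saline males 1 and 2, fentanyl libraries had numbers 1 to 6 and saline libraries 9 to 12, so exposure and number set coincided. DESeq2 called 53 higher and 34 lower genes over both sexes, 28 and 14 in males, 20 in females and 4 for the difference between the sexes. Limma voom called 663 and 343 over both sexes and 50 and 34 in males, and surrogate variables 54 and 29. Males alone gave 1 lower gene, and females alone 65 genes. Without saline males 1 and 2, 57 genes were higher and 14 lower in males, and 752 and 474 over both sexes with 16 lists; without numbers 9 to 12, 582 and 373 in males. Striatal and myelin covariates left 8 higher and 3 lower genes, 6 and 1 of them among the 14, and called 17 lists, and the cholesterol list's median turned to 0.0375. Without fentanyl male 2 and saline male 3, 22 lists were called. These settings over both sexes, the covariates and the 2 libraries were chosen after seeing the data, and the cause of these shifts was not tested. Lists fell to 0 in each of the 3 comparisons with an estimated correlation and with fry. Fentanyl and saline males of the same replicate number had correlations of -0.0694 to 0.209, 2 of 6 above 0.1. Of the fentanyl males, 1 of 6 was closest to its own number. No pairing by replicate number was visible, which does not exclude a pairing by litter or handling. With the replicate block, 2 genes were higher (Spag6l and LOC100912028) and 0 lower over both sexes by edgeR, and 3 were higher in males. Leaving out each library gave 8 to 21 higher and 1 to 8 lower genes over both sexes (21 and 8 without saline male replicate 2, 1 lower without fentanyl male replicate 6 or fentanyl female replicate 1, 2 without fentanyl female replicate 2, saline male replicate 6 or saline female replicate 1, 3 without fentanyl male replicates 1, 2, 3 or 5 or saline male replicate 3), 4 to 8 higher (4 without saline male replicate 4) and 0 to 2 lower in males, 0 to 5 in females and 0 to 5 for the difference (5 in both without saline male replicate 5), 3 to 20 lists (20 without fentanyl male replicate 2, 16 without saline male replicate 3, 13 without saline male replicate 1, 5 without saline male replicate 6, 4 without fentanyl female replicate 2, 3 without saline female replicate 2) and 10 sex genes throughout. Rgs22, Lonrf3, Set, Magix and LOC120095044 each lost their call in some of these fits. RLE factors shifted the median log2 fold change by 0.00 and moved no count over 1.5 times, nor did removing the filter, which ended the call of Lonrf3 (adjusted p = 0.0632). As for depth, 93 counts of Spag6l stood for 3.90 CPM in saline male replicate 3 and 177 counts for 13.9 CPM in fentanyl male replicate 5, so genes near 1 CPM rest on few counts.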

Other observations

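The tests here were chosen after the data were seen. Levels of marker genes describe the tissue. Pde10a, of the striatal list alone (772 ± 309 CPM), was abundant in all libraries (SD, n = 16). So were Penk (1317 ± 720 CPM) and Drd1 (230 ± 75.9 CPM), which are on both the striatal and the amygdala list. Among amygdala markers absent from the striatal list, Calcrl (15.8 ± 6.25 CPM), Nts (8.39 ± 6.62 CPM) and Crh (4.45 ± 4.21 CPM) were lower, and Sst, which interneurons also express, stood at 101 ± 46.2 CPM. Slc17a7, which marks cortical and basolateral glutamatergic neurons, had a median of 1.16 CPM, and 68.1 CPM in saline male replicate 3. Mbp, a myelin gene of oligodendrocytes, was high at 8995 ± 4310 CPM.

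Saline males with library numbers 1 and 2 had 1477 genes higher and 1724 lower than those numbered 9 to 12. Adora2a was higher by 1.57 ± 0.25 on the log2 scale (adjusted p = 0.00185) and Penk by 1.75 ± 0.33 (adjusted p = 0.00429), whereas Mbp was lower by a log2 fold change of -1.63 ± 0.49 (adjusted p = 0.0326) and Pvalb, a marker of fast-spiking interneurons, by -2.62 ± 0.79 (adjusted p = 0.0320), by edgeR's quasi-likelihood test. Number 9, saline male replicate 3, went with 1 and 2 in Pvalb and Mbp: Pvalb had 36.8, 8.63 and 16.5 CPM in replicates 1 to 3 and 149 to 198 CPM in replicates 4 to 6, and Mbp had 2875, 4055 and 4777 CPM against 10252 to 15277 CPM.

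Spag6l and LOC100912028 are adjacent in the gene order and Efcab1 lies 12 places from Spag6l. The log2 CPM of Spag6l and LOC100912028 moved together within the fentanyl libraries (Pearson's r = 0.814, exact permutation p = 0.0197; Spearman's rho = 0.833, p = 0.0154; n = 8) and within the saline libraries (r = 0.957, p = 4.464e-04; rho = 0.833, p = 0.0154; n = 8), with adjusted p of 0.0197 and 8.929e-04. Leaving out the 2 libraries farthest from the median of Spag6l gave r of 0.671 and 0.817.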
